A study of Homo sapiens with 16 samples.

How the data were processed

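Gene expression was measured in 16 samples of SK-N-SH cells, a human neuroblastoma line, on 1-colour Human Genome U219 arrays hybridised with biotin-labelled total RNA. The labels give 4 groups of 4 samples, each called a biological replicate: untreated cells and cells exposed to 10 µM risperidone for 6, 24 or 48 h. The labels' protocols state that cells were grown for 48 h to near confluence before exposure, that RNA was extracted with Trizol, and that controls received the solvent DMSO only, at no more than 1% of the volume. The sample labels call the same controls untreated, and give no harvest time for them.

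The deposited values are log2 expression values per probe set, on the scale of robust multi-array average (RMA), the method named in the submitters' processing notes. That method corrects each array's background, equalises the distribution of intensities between arrays and summarises the probes of a probe set. The software and its version are not given in the sources used here. The values had 2 decimals, lay between 2.57 and 13.98 over the 16 arrays, held no missing entries and were not centred per gene. Because the distributions had been equalised, a change in the total amount of RNA per cell cannot be seen, and a large change of many genes in one direction can shift the others slightly the opposite way.

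The table held 49386 probe sets, 93 of them controls. GEO's platform annotation of 2019 gave a single gene symbol for 45253, several symbols for 1327 and none for 2713 others that were not controls. Through the Entrez identifier, 45172 of these single-symbol probe sets matched the RefSeq gene table, which changed 0 symbols, and 81 did not match and kept their symbol. Only single-symbol probe sets were named. Each of the 18239 genes was represented by its probe set with the highest mean over the 16 arrays, since 11822 genes had more than 1. The lowest 25% of genes by that mean were left out as dim, which left 13680 genes with a mean of at least 3.65. Some genes in the choice of named genes are not reported here. HTR2A was dim and was not tested.

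Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 16 arrays in 1 fit with a mean per group). Contrasts set each exposure against untreated and each pair of exposure times against each other. Benjamini-Hochberg adjustment ran within each contrast and the threshold was an adjusted p of 0.05. A moderated F test took the 3 contrasts with untreated together. Values after ± are standard errors from limma unless given as SD. Each group has n = 4 arrays, and that number limits the precision.

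Gene lists, 38 in all, were tested with limma's camera, which asks whether a list's members stand higher or lower than the other tested genes, with a preset correlation between genes of 0.01. Adjustment covered 114 tests for the contrasts with untreated and 114 for those between times. Camera with a correlation estimated for each list, camera on ranks and fry were alternatives. The lists took in markers of other cell types that a culture could hold. List members, tests, alternatives and the choice of named genes were fixed before the data were examined. Named were, for each contrast with untreated, the 8 largest rises and the 8 largest falls past the threshold with all 4 treated arrays outside the untreated range, members of smallest p of the lists, of which at most 2 a list were printed, and a short fixed set of genes of interest. For each contrast between times, the 5 largest differences in each direction were named.

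Correlations of log2 changes between contrasts that share the untreated arrays were set beside 100 simulations with no effect and beside the 6 ways of splitting the untreated arrays into pairs. The 3 prime to 5 prime differences of control transcripts were compared by exact two-sided permutation tests over 70 arrangements, whose smallest possible p is 0.0286.

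Alternatives to the settings above were the mean of a gene's probe sets, every probe set tested by itself, no filter or a stricter filter of 50% on dim genes, subtraction of each array's median, quantile normalization applied again, cyclic loess, eBayes with trend and robust options, array weights, the replicate number as a block, only the 8 arrays compared, adjustment over the 3 contrasts together, an adjusted p of 0.01, a minimum change of 1.5-fold, and each array left out in turn. After the data had been seen, a fit without the untreated arrays for the contrasts between times, and a centring of each array on the mean of its adrenergic identity genes, were added.

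The procedure was tested on simulated values with the means and spreads of the 13680 genes. For a simulated 6 h contrast with 50 genes changed at each size, it recovered 74.0% of genes changed by 1.25-fold, 92.0% at 1.5-fold, and 100% at 2-fold and at 4-fold, with 11 false calls among 194. A simulated 24 h contrast without change gave 0 calls. Both lists of 20 genes shifted by 1.25-fold were recovered at 6 h and 0 of the other simulated lists were called. The simulation took over the means and spreads of genes but not the correlations between them. In the real data the estimated correlation was 0.238 for the mesenchymal list and 0.264 for TGF-beta targets. The simulation therefore cannot tell how often lists of correlated genes are called falsely. It also changed far fewer genes than the 7291 called in the real 6 h contrast, with as many rises as falls, and did not repeat the normalization. Its rates of recovery and of false calls may thus differ from those of the real contrasts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.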

Results

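SK-N-SH is a human neuroblastoma line whose cultures are known to hold neuroblast-like, adrenergic cells beside flat, substrate-adherent, mesenchymal cells. The study asked how expression in these cells responds over time to risperidone, an antipsychotic drug that blocks dopamine and serotonin receptors. Total RNA from untreated cells and from cells exposed to 10 µM risperidone for 6, 24 and 48 h was measured on Human Genome U219 arrays, with 4 arrays in each of the 4 groups. All values are log2 RMA values as deposited, and 13680 genes were tested. Array medians lay between 4.5 and 4.62. The labels call the arrays biological replicates without describing separate cultures, so p-values measure the spread between these samples. Controls are called untreated in the labels, while the protocol gives them the DMSO vehicle, and their harvest time is not given, so the same 4 arrays served as the reference for every exposure time.

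The untreated arrays stood apart from all 12 treated arrays. On the first principal component, which held 74.8% of the variance, they lay between -50.0 and -46.3 and the treated arrays between 12.1 and 20.2. The second component, with 10.2%, parted the 48 h arrays, at 15.7 to 17.1, from the 24 h arrays, at -6.54 to -5.90, and the 6 h arrays, at -11.9 to -9.79. Pearson correlations over the 13680 tested genes were 0.996 to 0.999 within groups, 0.968 to 0.978 between untreated and treated arrays, and 0.997 to 0.998 between 6 h and 24 h. No pair of arrays held the same values in more than 4.55% of these genes.

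**Figure D1:**
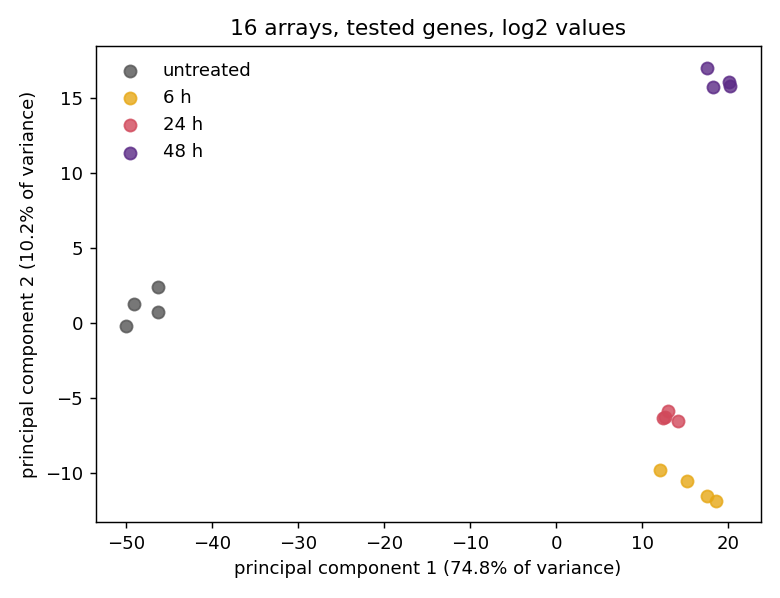
Principal component scores of the 16 arrays (points) over the 13680 tested genes, coloured by group, with the share of variance on each axis. Untreated arrays lie at or below -46.3 on the first component and the 12 treated arrays at 12.1 or above, and the 48 h arrays lie above 15 on the second.

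Mesenchymal genes fell at 6 h. Of the 23 measured markers of the substrate-adherent cell identity, 21 fell and 0 rose, with a median change of -2.47 (limma camera, adjusted p = 6.21e-22). The homeobox gene PRRX1 fell by 5.10 ± 0.14, the fibronectin gene FN1 fell by 3.30 ± 0.09, and the intermediate filament gene VIM fell by 1.24 ± 0.06, the last from 13.3 ± 0.09 to 12.1 ± 0.09 (SD, n = 4). Of 24 collagens and other matrix genes, 21 fell and 2 rose, with a median of -0.996 (adjusted p = 1.4e-15). COL6A3 fell by 4.20 ± 0.11 and COL1A1 fell by 3.51 ± 0.10. Among 14 targets of the transcription regulators YAP and TEAD, 11 fell and 1 rose, with a median of -1.56 (adjusted p = 3.11e-08). Their member CCN2, a secreted matrix-associated protein that the mesenchymal list also held, had the largest fall of all genes, -5.62 ± 0.17, and the receptor kinase AXL fell by 3.90 ± 0.11. Adjusted over the list alone, the counts of these lists were the same, and the calls held with an estimated correlation (adjusted p = 0.0303, 0.0303 and 0.0315). Other tested probe sets fell less for PRRX1 (-1.86), AXL (-1.13), CCN2 (-4.33), COL6A3 (-3.44) and COL1A1 (-2.77 to -1.84).

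Further genes of large fall at 6 h were the transcription factor FOXD1 (fell by 5.03 ± 0.09), the matrix protein gene EFEMP1 (fell by 4.70 ± 0.09), TMEM200A (fell by 4.61 ± 0.12), SRPX (fell by 4.43 ± 0.11) and the axon guidance cue SLIT2 (fell by 4.39 ± 0.09). The other tested probe set of TMEM200A changed by -1.76, and those of EFEMP1 by -5.24 to -2.66. Altogether 97 genes fell by at least 8-fold and 0 rose by as much. In treated arrays CCN2 averaged 3.18 and FOXD1 3.88, near the lowest value of the table, 2.57, so that folds of such genes depend on the bottom of the scale.

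Genes of catecholamine handling, synaptic vesicles and adrenergic identity rose at 6 h, while the lists of neurite growth, dopamine signalling and monoamine receptors did not pass (adjusted p = 0.739, 0.967 and 0.407). The largest rise of all genes was that of the serotonin receptor gene HTR1E, 2.70 ± 0.06 (from 5.70 ± 0.09 to 8.41 ± 0.12, SD, n = 4). The neuropeptide Y receptor gene NPY2R rose by 2.36 ± 0.10, EPB41L4B by 2.28 ± 0.04, the glutamate transporter gene SLC1A1 by 2.11 ± 0.10 and the synapse organiser CBLN2 by 1.87 ± 0.09. For SLC1A1 and CBLN2 the other tested probe set rose less, by 0.28 and 0.29, and those of EPB41L4B rose by 0.72 to 2.02. Of 13 genes of catecholamine synthesis, storage and breakdown, 10 rose and 0 fell, with a median of 0.41 (adjusted p = 0.000996, and adjusted p = 0.0378 with an estimated correlation). The vesicular monoamine transporter gene SLC18A1 rose by 1.80 ± 0.05 and DBH, which makes noradrenaline from dopamine, by 1.16 ± 0.07. Synaptic vesicle and release genes rose in 19 of 22 cases with 0 falls (median 0.41, adjusted p = 0.00014, and adjusted p = 0.0336 with an estimated correlation), RAB3A by 0.86 ± 0.06 and SYP by 1.09 ± 0.08. Other probe sets of RAB3A changed by 0.04 to 0.69 and those of SYP by 0.10 to 0.26. Adrenergic identity markers rose in 16 and fell in 2 of 20 cases (median 0.31, adjusted p = 0.00735, and adjusted p = 0.0372 with an estimated correlation), with EYA1 higher by 1.31 ± 0.05 while the granule protein gene SCG2 fell by 1.14 ± 0.06. Adjusted over the list alone, 17 adrenergic markers rose and 3 fell, and the counts of the catecholamine and synapse lists were the same. Neuronal ion channels and glutamate or GABA receptors rose in 13 and fell in 2 of 20 cases (median 0.31, adjusted p = 0.0463, but adjusted p = 0.164 with an estimated correlation), with the same counts adjusted over the list alone. CHRNA3 rose by 0.98 ± 0.05 and SCN9A fell by 1.33 ± 0.07. The ion channel call was also lost without any 1 of untreated replicates 2, 3 and 4 and 6 h replicates 1 and 3 (adjusted p = 0.0509 to 0.0681).

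Genes of cholesterol synthesis and uptake rose at 6 h in 19 of 20 measured cases with 0 falls (median 0.53, camera adjusted p = 4.84e-06, and adjusted p = 0.0336 with an estimated correlation). Squalene epoxidase, SQLE, rose by 0.65 ± 0.04 and HMGCS1, which makes the precursor of mevalonate, by 0.76 ± 0.07. Integrated stress response genes, targets of ATF4, rose in 18 and fell in 1 of 24 cases (median 0.26, adjusted p = 0.00439, but adjusted p = 0.208 with an estimated correlation). The secreted glycoprotein gene STC2 rose by 1.248 ± 0.09 and asparagine synthetase, ASNS, by 0.68 ± 0.05, and DDIT3, a stress-induced transcription factor, rose by 0.42 ± 0.09. Hypoxia-induced and glycolytic genes rose in 16 and fell in 3 of 24 cases (median 0.36, adjusted p = 0.0016, but adjusted p = 0.0652 with an estimated correlation). The glycolytic ALDOC rose by 1.20 ± 0.06 and the carbonic anhydrase gene CA12 fell by 3.32 ± 0.12 (other probe sets -3.36 to -0.74). Unfolded protein response genes fell in 11 and rose in 4 of 19 cases (median -0.19, adjusted p = 0.00693, but adjusted p = 0.151 with an estimated correlation). The chaperone gene PDIA4 fell by 0.45 ± 0.05. Lysosomal genes fell in 10 and rose in 4 of 23 cases (median -0.08, adjusted p = 0.013, but adjusted p = 0.151 with an estimated correlation). LAMP2 fell by 0.91 ± 0.07 and NPC2, which moves cholesterol out of lysosomes, fell by 0.72 ± 0.06. Adjusted over the list alone, 5 lysosomal genes rose and 10 fell, and the other counts of these lists were the same.

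Metal-handling genes were lower at 6 h, and further lists shifted down in calls that were lost with an estimated correlation. Metallothioneins and other metal-handling genes fell in 7 and rose in 2 of 12 cases (median -0.30, adjusted p = 0.000265, and adjusted p = 0.0303 with an estimated correlation). The metal-binding MT2A fell by 2.56 ± 0.09 from 12.9. Targets of NF-kappaB fell in 7 and rose in 1 of 13 cases (median -0.22, adjusted p = 0.00496, but adjusted p = 0.0652 with an estimated correlation). The adhesion molecule gene VCAM1 fell by 3.18 ± 0.14 (other probe set -2.06) and the chemokine gene CCL2 fell by 2.46 ± 0.14. Interferon-stimulated genes fell in 6 and rose in 3 of 17 cases (median -0.03, adjusted p = 0.0386, but adjusted p = 0.083 with an estimated correlation), and without any 1 of untreated replicates 1, 2 and 3 and 6 h replicate 1 the call was lost (adjusted p = 0.0506 to 0.0717). TGF-beta targets fell in 5 and rose in 3 of 11 cases (median -0.18, adjusted p = 0.00893, but adjusted p = 0.262 with an estimated correlation). LTBP2 fell by 2.46 ± 0.10 and TGFBI fell by 2.05 ± 0.10. WNT pathway genes fell in 7 and rose in 4 of 15 cases (adjusted p = 0.00957 for a downward shift, but adjusted p = 0.0747 with an estimated correlation), where the median was 0.075 and the mean -0.61, and DKK2 fell by 3.73 ± 0.12. Immediate early genes fell in 9 and rose in 5 of 22 cases (median -0.13, adjusted p = 0.00496, but adjusted p = 0.119 with an estimated correlation). IER3 fell by 3.14 ± 0.10, while FOS did not pass (-0.23 ± 0.11, limma adjusted p = 0.0878). FOS passed without untreated replicate 4 (-0.35) or 6 h replicate 4 (-0.29), with cyclic loess (-0.33) and with the mean of its probe sets (-0.18). Targets of p53 fell in 12 and rose in 3 of 19 cases (median -0.38, adjusted p = 0.000493, but adjusted p = 0.126 with an estimated correlation). The death receptor gene FAS fell by 2.23 ± 0.13 and the cell cycle inhibitor CDKN1A fell by 1.04 ± 0.09. Mitotic genes fell in 16 and rose in 1 of 25 cases (median -0.22, adjusted p = 1.17e-05, but adjusted p = 0.0791 with an estimated correlation). CDC20 fell by 0.59 ± 0.05 (other probe sets -0.495 to 0.127) and MKI67 fell by 0.39 ± 0.09. Adjusted over the list alone, 10 immediate early genes fell, and the other counts of these lists were the same.

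Over all genes at 6 h, limma called 7291 of 13680 past an adjusted p of 0.05, 5008 higher and 2283 lower, and of these 81 rose and 572 fell by at least 2-fold. The split depends on the scaling. The 68.7% of calls that were higher became 73% with array medians subtracted and 65.5% with renewed quantile normalization. Cyclic loess gave 49.4% (3151 higher and 3223 lower). It left a median change of 0.00968, against 0.0925 as deposited, so a nearly even split follows largely from the method. Centring each array on its adrenergic genes, an alternative chosen after seeing the data, gave 1291 higher and 7026 lower. That centring lowers every change by 0.26 at 6 h, 0.31 at 24 h and 0.38 at 48 h, so smaller rises turn into falls by construction. It thereby turns the sign of the medians of the ATF4 and WNT lists at 6 h, the ATF4 and ion channel lists at 24 h and the hypoxia list at 48 h. With the mean of each gene's probe sets, the interferon, ion channel and WNT calls at 6 h were lost (adjusted p = 0.154, 0.177 and 0.0527), and the WNT call was lost on ranks (adjusted p = 0.216). The ion channel call was also lost with no filter on dim genes, with the dimmer 50% left out, with each array's median subtracted, with trended and robust eBayes and with replicates as blocks (adjusted p = 0.0511 to 0.226). Renewed quantile normalization and cyclic loess ended the interferon call (adjusted p = 0.0509 and 0.0557), and with the dimmer 50% of genes left out the mean of its remaining 5 genes turned sign, from -0.27 to 0.03 (adjusted p = 0.79).

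**Figure D2:**
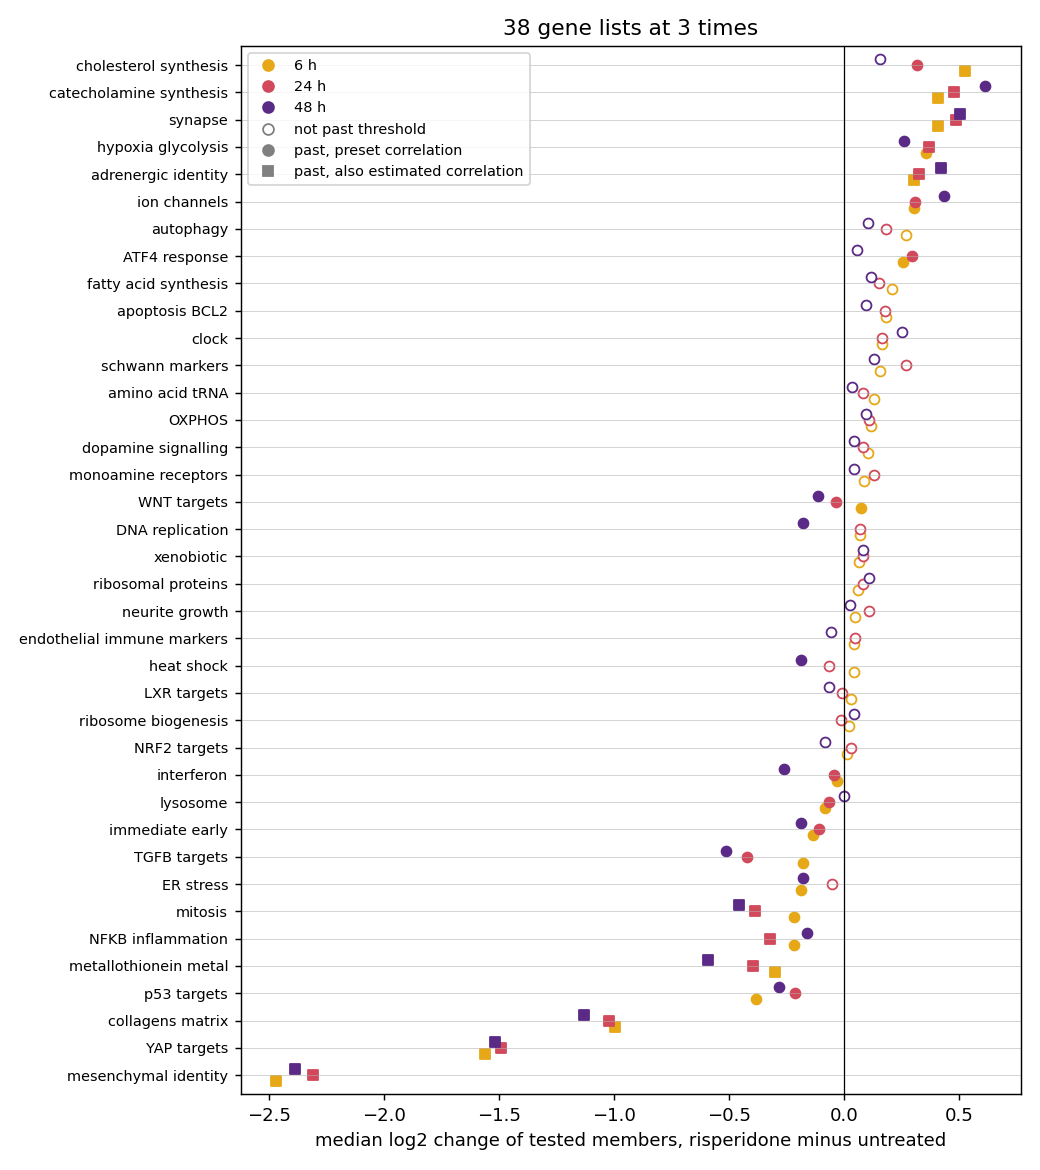
Median log2 change against untreated (horizontal axis) of the tested members of 38 gene lists (vertical axis) at 6, 24 and 48 h (colours). Filled symbols passed an adjusted p of 0.05 in limma's camera and squares passed with an estimated correlation too; mesenchymal markers have the lowest medians, -2.47, -2.31 and -2.39.

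At 24 h the mesenchymal and matrix genes were again low. Mesenchymal markers fell in 21 of 23 cases with 0 rises (median -2.31, camera adjusted p = 6.21e-22, and adjusted p = 0.0303 with an estimated correlation). FN1 fell by 3.27 ± 0.09 and VIM fell by 1.31 ± 0.06. Collagens and matrix genes fell in 21 and rose in 1 of 24 cases (median -1.02, adjusted p = 1.4e-15, and adjusted p = 0.0303 with an estimated correlation). YAP and TEAD targets fell in 11 and rose in 1 of 14 cases (median -1.49, adjusted p = 3.11e-08, and adjusted p = 0.0315 with an estimated correlation). CCN2 fell by 5.35 ± 0.17. The hyaluronan synthase gene HAS2 fell by 4.23 ± 0.09 and the integrin gene ITGA6 fell by 4.08 ± 0.17, while their other probe sets changed by -2.75 to -1.60 and by -4.61 to -2.08. Metal-handling genes fell in 8 and rose in 2 of 12 cases (median -0.40, adjusted p = 0.000186, and adjusted p = 0.0303 with an estimated correlation). The counts of these 4 lists were the same adjusted over the list alone.

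At 24 h HTR1E rose by 2.91 ± 0.06 and the potassium channel gene KCNH1 by 2.25 ± 0.08. The sterol exporter gene ABCG1 rose by 2.07 ± 0.09 (other probe sets 0.35 to 2.27). The dopamine receptor gene DRD2, a target of risperidone, rose by 0.95 ± 0.07, from 4.66 ± 0.15 to 5.602 ± 0.08 (SD, n = 4). It rose by 0.84 ± 0.07 at 6 h and 0.83 ± 0.07 at 48 h. Catecholamine genes rose in 9 of 13 cases with 0 falls (median 0.48, adjusted p = 0.000465, and adjusted p = 0.0336 with an estimated correlation), DBH by 1.34 ± 0.07, and synaptic genes in 18 of 22 with 0 falls (median 0.49, adjusted p = 0.000151, and adjusted p = 0.0336 with an estimated correlation). Adrenergic markers rose in 17 and fell in 3 of 20 cases (median 0.33, adjusted p = 0.00496, and adjusted p = 0.0336 with an estimated correlation). Ion channel genes rose in 11 and fell in 1 of 20 cases (median 0.31, adjusted p = 0.0149, but adjusted p = 0.115 with an estimated correlation). These counts were the same adjusted over the list alone. The neurite growth, dopamine signalling and monoamine receptor lists did not pass at 24 h (adjusted p = 0.583, 0.943 and 0.332).

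Cholesterol genes rose at 24 h in 14 of 20 cases with 0 falls (median 0.32, adjusted p = 0.00144, but adjusted p = 0.103 with an estimated correlation), and 15 rose adjusted over the list alone. SQLE rose by 0.49 ± 0.04 (other probe sets -0.0975 to 0.5) and the feedback regulator INSIG1 by 0.56 ± 0.06. ATF4 targets rose in 17 and fell in 1 of 24 cases (median 0.30, adjusted p = 0.00507, but adjusted p = 0.219 with an estimated correlation). Hypoxia and glycolysis genes rose in 17 and fell in 1 of 24 cases (median 0.37, adjusted p = 0.000265, and adjusted p = 0.0372 with an estimated correlation), the pyruvate dehydrogenase kinase gene PDK1 by 1.00 ± 0.05. Mitotic genes fell in 21 of 25 cases with 0 rises (median -0.39, adjusted p = 1.27e-10, and adjusted p = 0.0315 with an estimated correlation). CDC20 fell by 0.83 ± 0.05 (other probe sets -0.71 to 0.15) and CENPF fell by 1.01 ± 0.08. The counts of these 3 lists were the same adjusted over the list alone. NF-kappaB targets fell in 7 of 13 cases with 0 rises (median -0.32, adjusted p = 0.00141, and adjusted p = 0.0372 with an estimated correlation) and TGF-beta targets in 8 of 11 with 3 rises (median -0.42, adjusted p = 0.0011, but adjusted p = 0.151 with an estimated correlation). ID1 fell by 0.68 ± 0.05. Both counts were the same adjusted over the list alone. Targets of p53 fell in 11 and rose in 3 of 19 cases (median -0.21, adjusted p = 0.0016, but adjusted p = 0.154 with an estimated correlation), and WNT genes fell in 7 and rose in 5 of 15 (median -0.04, adjusted p = 0.00735, but adjusted p = 0.0652 with an estimated correlation), both with the same counts adjusted over the list alone. Interferon genes fell in 7 and rose in 3 of 17 cases (median -0.04, adjusted p = 0.0222, but adjusted p = 0.0652 with an estimated correlation), the same adjusted over the list alone. Immediate early genes fell in 9 and rose in 5 of 22 cases, 6 rising adjusted over the list alone (median -0.11, adjusted p = 0.00863, but adjusted p = 0.142 with an estimated correlation). Lysosomal genes fell in 7 and rose in 5 of 23 cases, 8 falling adjusted over the list alone (median -0.06, adjusted p = 0.0145, but adjusted p = 0.151 with an estimated correlation). The unfolded protein response list did not pass at 24 h (6 rose and 7 fell of 19, 9 falling adjusted over the list alone, median -0.05, adjusted p = 0.286).

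Over all genes at 24 h, limma called 7134, 4823 higher and 2311 lower, with 122 rises and 534 falls of at least 2-fold. The 67.6% of calls that were higher became 71.7% with array medians subtracted and 64.8% with renewed quantile normalization. Cyclic loess gave 49.5% (3183 higher and 3247 lower), again largely by its method, since it left a median change of 0.0094. Adrenergic centring gave 1117 higher and 8323 lower. The interferon and ion channel calls were lost with the mean of probe sets (adjusted p = 0.108 and 0.22), that of immediate early genes with the dimmer 50% of genes left out (adjusted p = 0.07) and that of WNT genes on ranks (adjusted p = 0.164). Leaving out the dimmer 50% also ended the ion channel call (adjusted p = 0.18) and that of the interferon list, whose mean turned from -0.28 to 0.03 (adjusted p = 0.797).

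At 48 h the mesenchymal markers fell in 21 and rose in 1 of 23 cases (median -2.39, camera adjusted p = 3.64e-17, and adjusted p = 0.0303 with an estimated correlation). Collagens and matrix genes fell in 21 and rose in 1 of 24 cases, 22 falling adjusted over the list alone (median -1.13, adjusted p = 1.83e-12, and adjusted p = 0.0315 with an estimated correlation). YAP and TEAD targets fell in 11 and rose in 1 of 14 cases, 12 falling adjusted over the list alone (median -1.52, adjusted p = 3.08e-07, and adjusted p = 0.0336 with an estimated correlation). The protease inhibitor gene SERPINB7 fell by 4.38 ± 0.14 and the matrix metalloproteinase gene MMP3 fell by 4.29 ± 0.19. Metal-handling genes fell in 8 and rose in 2 of 12 cases (median -0.59, adjusted p = 0.000425, and adjusted p = 0.0303 with an estimated correlation). MT2A fell by 2.80 ± 0.09. Mesenchymal and metal-handling counts were the same adjusted over the list alone.

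Among the large rises at 48 h were 3.29 ± 0.06 for HTR1E, 3.04 ± 0.09 for NELL1 (other probe sets 1.36 to 1.98), 2.93 ± 0.08 for KCNH1 and 2.34 ± 0.11 for the neuronal adhesion gene CNTNAP4. Synaptic genes rose in 18 and fell in 1 of 22 cases (median 0.51, adjusted p = 0.000265, and adjusted p = 0.0372 with an estimated correlation), SNAP25 by 0.79 ± 0.05, and catecholamine genes rose in 9 and fell in 2 of 13 (median 0.62, adjusted p = 0.00389, but adjusted p = 0.0652 with an estimated correlation), DBH by 1.74 ± 0.07. The counts of both lists were the same adjusted over the list alone. Adrenergic markers rose in 16 and fell in 2 of 20 cases, 17 rising adjusted over the list alone (median 0.43, adjusted p = 0.00255, and adjusted p = 0.0315 with an estimated correlation), EYA1 by 1.60 ± 0.05. Ion channel genes rose in 14 and fell in 1 of 20 cases, the same adjusted over the list alone (median 0.44, adjusted p = 0.00629, but adjusted p = 0.0748 with an estimated correlation), with the glutamate receptor gene GRIA4 up by 1.65 ± 0.09 (other probe set 0.57). Hypoxia and glycolysis genes rose in 16 and fell in 2 of 24 cases, 4 falling adjusted over the list alone (median 0.26, adjusted p = 0.0149, but adjusted p = 0.137 with an estimated correlation). The cholesterol list no longer passed at 48 h (11 rose and 2 fell of 20, the same adjusted over the list alone, median 0.16, adjusted p = 0.142), although SREBF2, the regulator of these genes, rose by 0.60 ± 0.05. ATF4 targets did not pass at 48 h either (9 rose and 7 fell of 24, the same adjusted over the list alone, adjusted p = 0.943 in a downward test beside a median of 0.0575 and a mean of 0.0902). Nor did lysosomal genes (5 rose and 8 fell of 23, the same adjusted over the list alone, adjusted p = 0.181, with a median of 0.0025 and a mean of -0.0832).

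Cell division genes were lower at 48 h. DNA replication genes fell in 16 and rose in 1 of 26 cases (median -0.18, adjusted p = 8.59e-05, but adjusted p = 0.175 with an estimated correlation). Thymidine kinase TK1 fell by 0.91 ± 0.06 and the ribonucleotide reductase subunit RRM2 fell by 0.60 ± 0.05. This list had not passed at 6 h and 24 h (6 and 7 rose and 1 and 1 fell, 4 and 6 rising adjusted over the list alone, medians 0.0713 and 0.0687, adjusted p = 0.786 and 0.672). Mitotic genes fell in 21 of 25 cases with 0 rises (median -0.46, adjusted p = 2.77e-10, and adjusted p = 0.0322 with an estimated correlation). HMMR fell by 0.81 ± 0.05 and MKI67 fell by 0.69 ± 0.09. Heat shock genes fell in 10 of 15 cases with 0 rises (median -0.19, adjusted p = 0.000652, but adjusted p = 0.12 with an estimated correlation). The co-chaperone BAG3 fell by 2.54 ± 0.11 and HSPB1 fell by 1.04 ± 0.05. The heat shock list had not passed at the earlier times (4 and 2 rose and 4 and 3 fell, the same adjusted over the list alone, medians 0.0425 and -0.065, means -0.19 and -0.213, adjusted p = 0.286 and 0.0729). Unfolded protein response genes fell in 12 and rose in 3 of 19 cases (median -0.18, adjusted p = 0.00836, but adjusted p = 0.163 with an estimated correlation). Targets of p53 fell in 11 and rose in 4 of 19 cases (median -0.28, adjusted p = 0.000519, but adjusted p = 0.126 with an estimated correlation). DDB2 fell by 0.99 ± 0.05 and CDKN1A fell by 1.21 ± 0.09. NF-kappaB targets fell in 6 of 13 cases with 0 rises (median -0.16, adjusted p = 0.00736, but adjusted p = 0.0738 with an estimated correlation). TGF-beta targets fell in 7 and rose in 3 of 11 cases (median -0.51, adjusted p = 0.00731, but adjusted p = 0.242 with an estimated correlation). The inhibitory SMAD6 fell by 2.88 ± 0.12 on its brightest probe set, and its others changed by -0.595 to 0.045. Interferon genes fell in 9 and rose in 4 of 17 cases (median -0.26, adjusted p = 0.0165, but adjusted p = 0.0632 with an estimated correlation). Adjusted over the list alone, the counts of these 8 lists were the same. WNT genes fell in 7 and rose in 3 of 15 cases, 8 falling adjusted over the list alone (median -0.11, adjusted p = 0.0071, but adjusted p = 0.0652 with an estimated correlation). Immediate early genes fell in 11 and rose in 3 of 22 cases, 4 rising adjusted over the list alone (median -0.19, adjusted p = 0.00439, but adjusted p = 0.115 with an estimated correlation). FOS fell by 0.76 ± 0.11 (other probe sets -1.34 to 0.0375).

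Over all genes at 48 h, limma called 7794, 4920 higher and 2874 lower, with 232 rises and 612 falls of at least 2-fold. The 63.1% of calls that were higher became 64.7% with array medians subtracted and 60% with renewed quantile normalization. Cyclic loess gave 49.0% (3707 higher and 3858 lower), again largely by its method, since it left a median change of 0.00289. Adrenergic centring gave 1243 higher and 9699 lower. Calls of the interferon list were lost with the mean of each gene's probe sets (adjusted p = 0.0951) and with the dimmer 50% of genes left out (adjusted p = 0.502), as were those of the ion channel list (adjusted p = 0.118 and 0.307), and on ranks the TGF-beta and WNT calls were lost (adjusted p = 0.0609 and 0.0618). The mean of probe sets ended the WNT call too (adjusted p = 0.0501).

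Few genes differed between 24 h and 6 h. The lysosomal and melanosomal glycoprotein gene GPNMB was higher at 24 h by 1.31 ± 0.16, the muscarinic receptor gene CHRM3 by 0.87 ± 0.15 and the globin gene HBQ1 by 0.82 ± 0.07, while CRCP fell by 1.11 ± 0.14 (other probe sets -1.05 to 0.03) and the growth factor gene HDGF fell by 0.96 ± 0.06. The mitotic list shifted down from 6 h to 24 h (3 of 25 lower and 0 higher, 16 lower adjusted over the list alone, median -0.15, camera adjusted p = 1.59e-12, but adjusted p = 0.0871 with an estimated correlation). The cholesterol list shifted down too (5 of 20 lower and 0 higher, 11 lower adjusted over the list alone, median -0.17, adjusted p = 1.47e-10, but adjusted p = 0.0633 with an estimated correlation). The unfolded protein response list shifted up (3 of 19 higher and 0 lower, 5 higher adjusted over the list alone, median 0.09, adjusted p = 6.16e-06, but adjusted p = 0.158 with an estimated correlation). The hypoxia and glycolysis list shifted up by little (1 of 24 higher and 0 lower, 4 higher adjusted over the list alone, median 0.02, adjusted p = 0.0178, but adjusted p = 0.343 with an estimated correlation), a call lost without 24 h replicate 4 (adjusted p = 0.065) and with the mean of probe sets (adjusted p = 0.0693). ZFP36L1 was higher by 0.92 ± 0.15 on its brightest probe set, and its other tested probe sets changed by -0.25 to 0.11, and the mean of all its probe sets did not pass (adjusted p = 0.34). Limma called 329 genes, 212 higher and 117 lower. Array weights raised the count to 839, and it fell to 214, 191 and 197 without 6 h replicates 2, 3 and 4 and to 209, 164 and 208 without 24 h replicates 1, 2 and 3.

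Between 24 h and 48 h the glucose-responsive genes TXNIP and ARRDC4, which code for arrestin-like regulators of glucose uptake, changed by -3.79 ± 0.08 and -1.94 ± 0.05. TXNIP had been above untreated at 6 h by 0.31 ± 0.08, and at 48 h stood at 6.38 ± 0.21 (SD, n = 4) against 9.98 in untreated cells. The immediate early gene EGR1 fell by 2.21 ± 0.12 (other probe sets -2.50 to -0.03) and the glucocorticoid-induced kinase gene SGK1 fell by 1.28 ± 0.08, while DDIT3 rose by 1.5 ± 0.09 and the kinase gene LATS1 by 1.53 ± 0.07. DNA replication genes fell in 21 of 26 cases with 0 rises, the same adjusted over the list alone (median -0.34, camera adjusted p = 2.04e-11, but adjusted p = 0.173 with an estimated correlation). ATF4 targets fell in 14 and rose in 3 of 24 cases, 15 and 4 adjusted over the list alone (median -0.31, adjusted p = 0.000686, but adjusted p = 0.351 with an estimated correlation), so that DDIT3 moved against its list. Heat shock genes fell in 8 of 15 cases with 0 rises, 9 adjusted over the list alone (median -0.17, adjusted p = 0.00279, but adjusted p = 0.351 with an estimated correlation). Unfolded protein response genes fell in 8 of 19 cases with 0 rises, 9 falling and 1 rising adjusted over the list alone (median -0.14, adjusted p = 0.0134, but adjusted p = 0.352 with an estimated correlation), a call lost without 48 h replicate 4 (adjusted p = 0.0551). Targets of p53 fell in 9 and rose in 3 of 19 cases, 10 falling adjusted over the list alone (median -0.16, adjusted p = 0.0419, but adjusted p = 0.647 with an estimated correlation). That call was lost without any 1 of untreated replicates 1 and 3, 24 h replicates 1 and 4 and 48 h replicates 1 and 3 (adjusted p = 0.0504 to 0.065). It was also lost with the mean of probe sets, each array's median subtracted, renewed quantile normalization, array weights, replicates as blocks and ranks (adjusted p = 0.0509 to 0.199). AKAP6, which codes for an anchoring protein, rose by 1.89 ± 0.11 and ANKRD44 by 1.54 ± 0.12. Their other tested probe set gave 0.09, which did not pass, and 0.27, which did. Limma called 3907 genes, 1845 higher and 2062 lower, of which 17 and 7 differed by at least 2-fold.

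From 6 h to 48 h, TXNIP fell by 3.91 ± 0.08, ARRDC4 fell by 2.09 ± 0.05, SMAD6 fell by 2.19 ± 0.12 and the semaphorin receptor gene PLXNA4 fell by 1.70 ± 0.11. CHRM3 was higher by 1.73 ± 0.15, the adhesion gene FLRT1 by 1.63 ± 0.10 and the phosphodiesterase gene GPCPD1 by 1.61 ± 0.09 (other probe set 0.73). The other tested probe sets of SMAD6 and PLXNA4 changed less, by -0.40 to 0.01 and by -0.52 to 0.17. Cholesterol genes were lower in 13 of 20 cases with 0 higher, 15 lower and 1 higher adjusted over the list alone (median -0.35, camera adjusted p = 3.4e-06, but adjusted p = 0.158 with an estimated correlation). DNA replication genes were lower in 20 of 26 cases with 0 higher (median -0.32, adjusted p = 4.96e-10, but adjusted p = 0.199 with an estimated correlation) and heat shock genes in 10 of 15 with 0 higher (median -0.19, adjusted p = 0.00168, but adjusted p = 0.351 with an estimated correlation), both the same adjusted over the list alone. Mitotic genes were lower in 18 of 25 cases with 0 higher, 19 lower adjusted over the list alone (median -0.25, adjusted p = 7.63e-07, but adjusted p = 0.199 with an estimated correlation). ATF4 targets were lower in 14 and higher in 3 of 24 cases, the same adjusted over the list alone (median -0.26, adjusted p = 0.000947, but adjusted p = 0.351 with an estimated correlation). The adrenergic list shifted up, with 7 higher and 1 lower of 20, 8 higher adjusted over the list alone (median 0.08, adjusted p = 0.0275, but adjusted p = 0.173 with an estimated correlation). Limma called 4598 genes, 2279 higher and 2319 lower. The adrenergic call was lost with each array's median subtracted (adjusted p = 0.0538).

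**Figure D3:**
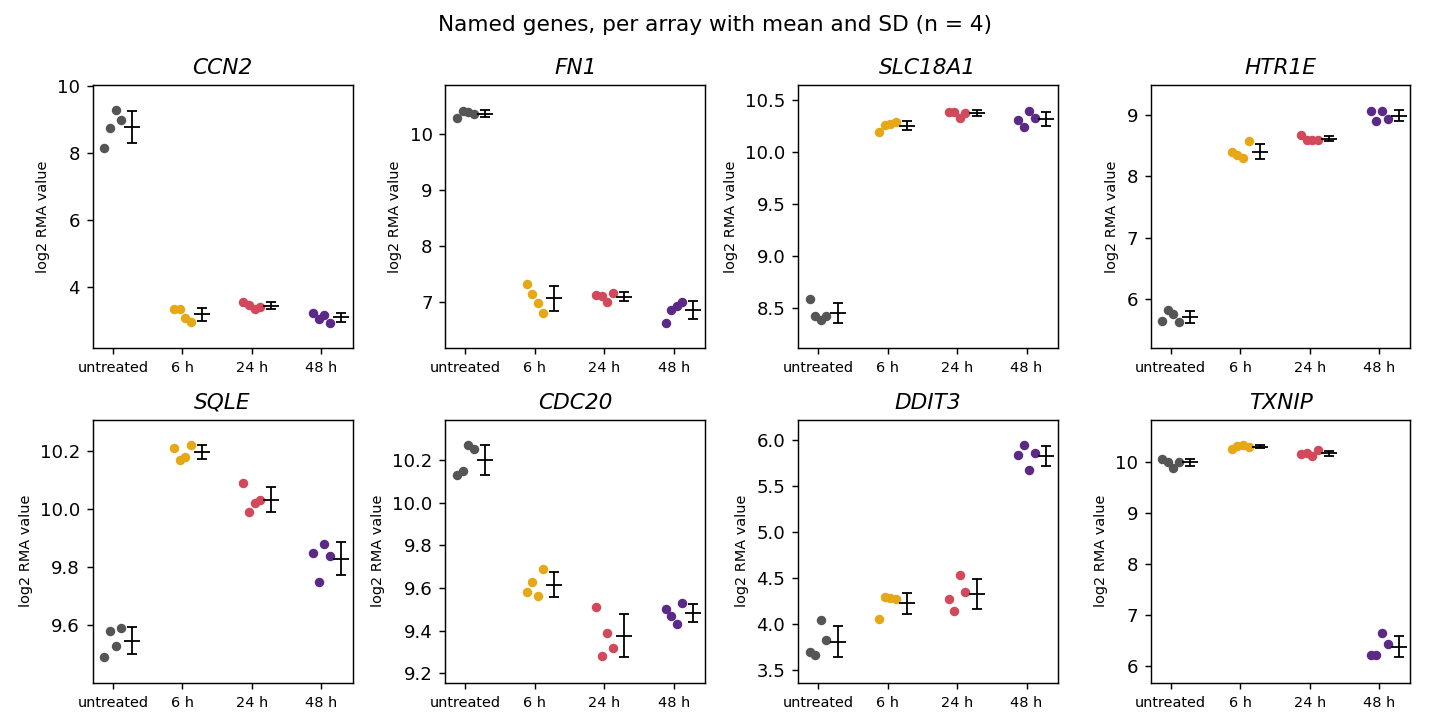
Log2 RMA values (vertical axes, a different range in each panel) of 8 named genes on each array (points) by group (horizontal axis), with the mean and SD of 4 arrays (black bars). CCN2 and FN1 are low at all 3 times, HTR1E is higher at 48 h (8.99) than in untreated cells (5.70), SQLE is highest at 6 h, and TXNIP is low at 48 h alone among the 4 groups.

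The mesenchymal genes FN1 and CCN2 were lower at all 3 times. Over the 3 contrasts with untreated, 3289 genes were higher and 1776 lower at all times, 67 were higher and 492 lower by at least 2-fold, and 65 were lower by at least 8-fold. Across the 13680 genes, which are not independent replicates, the changes at 6 h and 24 h correlated with r = 0.977, those at 6 h and 48 h with r = 0.915 and those at 24 h and 48 h with r = 0.934. The contrasts share their untreated arrays, which alone gives r = 0.50 in simulations with no effect. Split untreated arrays gave mean r = 0.950, 0.892 and 0.909, and the covariance exceeded the simulated one by 0.285, 0.296 and 0.287. At both 6 h and 24 h, 4126 genes were higher and 2017 lower. For 6 h and 48 h the figures were 3590 and 1887, and for 24 h and 48 h 3642 and 1937. These overlaps rest in part on the shared untreated arrays. In opposite directions went 7, 161 and 125 genes. The moderated F test over the 3 contrasts called 9118 genes, 66.7% of those tested. Where called genes had several tested probe sets, another passed in the opposite direction for 159 of 4745 at 6 h, 167 of 4670 at 24 h and 327 of 5131 at 48 h.

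RNA quality was compared through control transcripts probed at both ends. The 3 prime to 5 prime difference of ACTB was 2.22 ± 0.19 at 6 h against 1.77 ± 0.17 in untreated arrays (SD, n = 4, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 arrays allow, adjusted p = 0.257 over 9 comparisons). At 24 h it was 2.08 ± 0.10 (exact permutation p = 0.0571) and at 48 h 1.90 ± 0.17 (exact permutation p = 0.429). For GAPDH the difference was 0.12 ± 0.04 in untreated arrays and 0.09 to 0.10 in treated ones (exact permutation p = 0.229 to 0.514). For the added dap transcript it was 2.58 ± 0.11 in untreated arrays and 2.47 to 2.79 in treated ones (exact permutation p = 0.143 to 0.2).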

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

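The tests on cell shares, separate cultures, time in culture, single probe sets, glucose depletion and the make-up of the regroupings in this part were chosen after the results were seen, while the splits of the arrays were planned.

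The falls of mesenchymal and matrix genes and the rises of catecholamine, synaptic and adrenergic genes at all 3 times form the first pattern. Of these list calls, that of the catecholamine genes at 48 h was lost with an estimated correlation (limma camera adjusted p = 0.0652). A lower share of substrate-adherent cells as the whole cause of the rises would move every gene that is higher in the other cells the same way between times, whatever the profile of each cell type. Of the 75 members of the adrenergic, catecholamine, synaptic and ion channel lists, 55 were higher at 24 h than untreated. From 6 h to 48 h 28 of these passed, 20 rising and 8 falling. The one-sided exact binomial p was 4.92e-05 against a share of 0.05 of false calls, though genes are not independent. With array medians subtracted 9 of 29 fell, and with cyclic loess 8 of 26. These values argue against a lower share as the whole cause of the changes between 6 h and 48 h. They cannot decide the rises from untreated to 6 h, for which a lower share stays open. From 6 h to 48 h the mesenchymal mean changed by only 0.03 (exact permutation p = 0.686), so the shares may hardly have moved. Another change in the make-up of the cells stays open. As the whole cause of the falls, a lower share of substrate-adherent cells stays open too. On its reported probe set CCN2 would need a share at least 49.0-fold lower at 6 h. This is a lower bound for that probe set because its treated arrays averaged 3.18, near the lowest value of 2.57. The other tested probe set of CCN2 fell less (-4.325) and would need a smaller change of share. Cell counts are not given. The untreated arrays may also come from a separate culture or batch, which cannot be told apart from the treatment, because each group holds 1 condition. Among genes at least 2-fold lower at all times the ratio of the 6 h to the 48 h change had a median of 1.03 (quartiles 0.951 and 1.11). The falls of these genes were thus about as large at 6 h as at 48 h. Their choice leaves out falls that reached 2-fold only later, which favours a ratio near 1. A batch could also change RNA quality, but no 3 prime to 5 prime control difference passed (lowest adjusted p = 0.257 over 9 exact permutation tests, whose smallest possible p of 0.0286 leaves little room to pass). If the same cells were followed and no new transcript were made, the CCN2 fall would need a transcript half-life of at most 1.07 h, or 1.39 h on its other probe set, and that of COL1A1 at most 1.71 h, or 2.17 to 3.27 h on its others. Each of the 97 falls of at least 8-fold would need at most 2 h on the reported probe set. Time in culture or cell density could also contribute and cannot be told apart from the exposure, since the untreated arrays have no stated harvest time. The DMSO vehicle stays open too if the controls went without it, as their label of untreated may mean. A response of the cells to risperidone stays among the open explanations.

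Cholesterol synthesis genes, higher at 6 h and lower again by 48 h, form the second pattern. Their list mean rose by 0.49 from untreated to 6 h and fell by 0.29 (-0.2899) from 6 h to 48 h, each with an exact two-sided permutation p of 0.0286, the smallest possible. A change in the shares of adrenergic and mesenchymal cells as the cause of both steps would need both identity lists to turn back too. Instead the adrenergic mean rose by 0.26 and then by a further 0.12 (exact permutation p = 0.0286 for both). The mesenchymal mean changed by -2.42 and then by 0.03 (exact permutation p = 0.0286 and 0.686). A change of these shares as the cause of the rise to 6 h alone stays open. In limma's camera, which compares a list with the other genes, the 6 h to 48 h calls of the adrenergic and cholesterol lists were lost with an estimated correlation (adjusted p = 0.173 and 0.158), and the adrenergic call with array medians subtracted (adjusted p = 0.0538). A shift in other cells, such as cycling ones, was not tested and stays open. Time in culture or used medium could contribute and cannot be told apart from the exposure, since 0 untreated arrays have a stated harvest time. A response to risperidone stays open as well.

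TXNIP and ARRDC4, lower at 48 h than at 24 h, form the third pattern. A signal of single probe sets is argued against by the 7 tested probe sets of both genes, of which the smallest fall was -1.94. Glucose depletion is a candidate explanation that stays open. The mean of the unfolded protein response list changed by -0.1388 from 24 h to 48 h (exact two-sided permutation p = 0.0286), which decides nothing, since a mild depletion need not raise that list, and other stress genes went both ways over the same interval: DDIT3 rose by 1.5 while its list of ATF4 targets fell in 14 and rose in 3 of 24 cases (median -0.31, a call lost with an estimated correlation, adjusted p = 0.351). No table holds glucose levels.

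Chance was examined by refitting other splits of the same arrays. For genes against untreated, the real split gave 7291 at 6 h (highest other 0), 7134 at 24 h (0) and 7794 at 48 h (0). Only 1 of 35 splits, the real one, gave as many, the smallest share this test can give. Every other split mixes treated and untreated arrays, which widens the spread within groups and lowers its count. The counts therefore show that the groups stand apart, and chance is argued against without being excluded. For the gene lists the real counts were 20, 19 and 19 and the highest others 17 each, with 1 of 35 splits as large in every case. A mixed split thus gave nearly as many list calls as the real one, so the count of lists by itself says little. Mixed splits can keep part of the group difference, so they are not a reference with no effect. Between times the real counts were 329, 3907 and 4598 and the highest others 0, 2 and 2, again with 1 of 35 splits as large. For the moderated F test 1 of 100 regroupings, the real one, reached 9118; the highest other, 5165, came from the 1 regrouping that kept all 4 untreated arrays in 1 group. The 12 that kept 3 of them together gave at most 4 genes and the 68 and 18 that kept 2 and 1 gave 0, so the high count goes with the untreated arrays standing apart.

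Exposure times differed from each other in 329 genes between 24 h and 6 h, 3907 between 48 h and 24 h and 4598 between 48 h and 6 h, each by limma's test of the difference itself. From 6 h to 24 h, list means shifted by -0.17 for cholesterol synthesis, 0.11 for the unfolded protein response, 0.074 for hypoxia and glycolysis and -0.15 for mitosis, calls that were lost with an estimated correlation (limma camera adjusted p = 0.0633, 0.158, 0.343 and 0.0871). From 24 h to 48 h they shifted by -0.20 for ATF4 targets, -0.33 for DNA replication, -0.14 for the unfolded protein response, -0.18 for heat shock and -0.13 for p53 targets, all lost with an estimated correlation (adjusted p = 0.351, 0.173, 0.352, 0.351 and 0.647). From 6 h to 48 h the shifts were 0.12 for adrenergic identity, -0.20 for ATF4 targets, -0.29 for cholesterol synthesis, -0.32 for DNA replication, -0.21 for heat shock and -0.23 for mitosis, and these were lost with it too (adjusted p = 0.173, 0.351, 0.158, 0.199, 0.351 and 0.199). Some named genes lay on opposite sides of untreated at 2 times. The histone gene H2AC20 differed by -0.71 between 24 h and 6 h and by -1.13 between 48 h and 6 h, LATS1 by 1.53 between 48 h and 24 h, TXNIP by -3.91 between 48 h and 6 h, ARRDC4 by -1.94 and -2.09 between 48 h and 24 h or 6 h, and GPCPD1 by 1.37 and 1.61 between the same times.

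Single arrays stood apart from the other 3 of their group, by Dixon's criterion, in 31 of 620 groups of values checked, and chance gives about 1 in 20, which is 31. List means so placed were the aminoacyl-tRNA synthetases in 24 h replicate 1 (10.2), ion channels in 6 h replicate 2 (6.28), LXR targets in 24 h replicate 4 (5.58), ribosomal proteins in 48 h replicate 4 (13.3), Schwann cell markers in 48 h replicate 4 (6.31) and xenobiotic response genes in 6 h replicate 2 (5.70). In untreated replicate 1 the genes were SLC7A11 (5.88), VIM (13.16), HDGF (11.68) and H2AC20 (7.30), and in untreated replicate 2 ZFP36L1 (8.48) and LATS1 (3.94). At 6 h they were COL6A3 (4.82), RAB3A (7.15), DDIT3 (4.05) and DDB2 (7.47) in replicate 1 and SGK1 (9.92) in replicate 4. At 24 h they were HTR1E (8.67), COL1A1 (5.08), CCL2 (3.78), CLSTN2 (6.58) and TAOK1 (7.62) in replicate 1, SLC18A1 (10.33) and NRP1 (6.17) in replicate 3, and IFI44 (3.91), ITGA6 (6.74) and CENPF (9.15) in replicate 4. At 48 h they were LEF1 (3.03) in replicate 2, IFI44 (3.93) in replicate 3, and SYP (8.56) and SNAP25 (11.26) in replicate 4. Since values have 2 decimals, such a flag can follow from rounding alone. The rest of the group stood at 11.69 for HDGF and at 3.05 for LEF1.

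Probe sets without a gene name here, which enter no comparison above, also differed from untreated: of 2445 tested, limma called 931 at 6 h, 939 at 24 h and 1151 at 48 h.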

How the results depend on the processing

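The fit without untreated arrays and the centring on adrenergic genes were tests chosen after the results were seen. Of 5602 values of named genes under alternatives, 5597 kept direction and side of the threshold, 1 lost its call (ZFP36L1 between 24 h and 6 h, 0.13 with the mean of its probe sets, limma adjusted p = 0.34) and 4 gained 1 (FOS at 6 h). Of 2041 values of gene lists 1943 kept both and 98 lost the call, 48 of them with an estimated correlation. Most named genes were chosen for large changes or small p in these same arrays. That they kept their calls therefore says little about the other called genes. Named genes that a setting left untested are not counted: 148 of 210 values remained with the dimmer 50% left out and 204 with the mean of probe sets. With the dimmer 50% of genes left out, the mean of the interferon list turned from -0.27 and -0.28 to 0.03 and 0.03 at 6 h and 24 h, over the 5 members left (limma camera adjusted p = 0.79 and 0.797). Genes near the bottom of the scale limit what folds can be read, and the cause of the changes below was not tested except where a stricter threshold passes fewer genes by construction.

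Lists past the threshold numbered 8, 10 and 7 at 6, 24 and 48 h with an estimated correlation and 33, 33 and 35 with fry, which tests each list by itself. A minimum of 1.5-fold left 1528, 1557 and 2093 genes against untreated, 2465 for the F test, and 46, 229 and 356 between 24 h and 6 h, 48 h and 24 h, and 48 h and 6 h. An adjusted p of 0.01 left 113, 2439 and 2997 for the same contrasts between times. Between 24 h and 6 h, array weights gave 839 genes, every probe set by itself 658, and leaving out 1 array 164 to 378. Correlations of changes (6 h with 24 h, 6 h with 48 h, 24 h with 48 h) were 0.971, 0.904 and 0.926 with the mean of probe sets and 0.950, 0.892 and 0.909 with untreated arrays split. Without a filter the first was 0.972, and without the dimmer 50% of genes the others were 0.899 and 0.919. Without untreated arrays in the fit, the contrasts between times gave 409, 4325 and 5061 genes, and adrenergic centring gave 8317, 9440 and 10942 against untreated.

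The replicate numbers showed no clear pairing of the arrays, though a weak one is not excluded. The deviations of the 24 same-numbered pairs correlated at -0.152 to 0.181, 8 of them over 0.1. Their mean was 0.0383, against -0.0121 for pairs of other numbers. Of 16 arrays, 6 correlated best with their own number. The replicate number as a block gave 7325, 7187 and 7830 genes against untreated, 327, 3946 and 4640 between times, 9151 for the F test, and 19 lists at each time.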

Other observations

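No tests in this part were chosen after the results were seen. Single receptor genes and single sterol exporter genes moved in opposite directions, in lists that did not pass. The histamine receptor gene HRH1 fell by 2.08 ± 0.13 at 6 h (other probe sets -1.46 and -1.0), while HTR1E and DRD2 rose. Of the 28 monoamine receptor genes of the list with a single-symbol probe set, 14 were dim and were not tested. The tested members did not pass as a list (5, 6 and 4 of 14 rose and 1, 1 and 3 fell at 6, 24 and 48 h, the same adjusted over the list alone, limma camera adjusted p = 0.407, 0.332 and 0.628). ABCG1 rose by 1.30 ± 0.09 at 6 h (other probe sets 0.20 to 1.38) and the related exporter ABCA1 fell by 1.52 ± 0.16, and LXR targets did not pass (3, 2 and 2 of 9 rose and 3, 3 and 2 fell, the same adjusted over the list alone, adjusted p = 0.583, 0.604 and 0.672), with a downward test, medians of 0.03, -0.01 and -0.06 and means of -0.09, 0.04 and 0.04. The clock genes BHLHE41 and NPAS2 changed by -2.17 ± 0.13 and -1.47 ± 0.10 at 6 h (other NPAS2 probe set -0.99) and DBP rose by 1.23 ± 0.09 at 48 h, in a list that did not pass (8, 7 and 10 of 17 rose and 4, 5 and 4 fell, the same adjusted over the list alone, adjusted p = 0.967, 0.786 and 0.489), with medians of 0.17, 0.17 and 0.25 and a mean of -0.06 at 6 h. Among genes of neurite growth STMN4 rose by 1.02 ± 0.05 at 6 h (other probe sets 0.55 and 1.20) and MAPT, which codes for tau, by 1.91 ± 0.06 at 48 h (other probe sets 0.20 to 2.17, 3 of 4 past the threshold), while NRP1 fell by 3.12 ± 0.09 at 6 h on its brightest probe set (others -1.66 to 0.00). That list did not pass (12, 10 and 12 of 25 rose and 8, 9 and 10 fell, 8, 10 and 11 adjusted over the list alone, adjusted p = 0.739, 0.583 and 0.616), its medians being 0.05, 0.11 and 0.03 and its means -0.33, -0.31 and -0.30.

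NRF2 targets did not pass either (2, 2 and 3 of 15 rose and 4, 4 and 6 fell, the same adjusted over the list alone, limma camera adjusted p = 0.193, 0.318 and 0.118, medians 0.01, 0.03 and -0.08, means -0.20, -0.15 and -0.28), although NQO1 fell by 1.15 ± 0.06 at 6 h and SLC7A11 fell by 1.247 ± 0.13, the latter with other probe sets at -2.18 and 0.18. Genes of the BCL2 family rose in 7, 7 and 6 and fell in 2, 3 and 4 of 14 cases (8 rising at 24 h and 5 falling at 48 h adjusted over the list alone, adjusted p = 0.551, 0.551 and 0.734), PMAIP1 falling by 0.92 ± 0.06 at 48 h, where the median was 0.10 and the mean -0.01. Autophagy genes rose in 12, 11 and 8 and fell in 2, 2 and 5 of 19 cases, the same adjusted over the list alone (adjusted p = 0.256, 0.24 and 0.576). Fatty acid synthesis genes rose in 8, 7 and 7 and fell in 0, 0 and 1 of 14 cases, 9, 8 and 7 rising adjusted over the list alone (adjusted p = 0.0591, 0.154 and 0.286). Respiratory chain genes rose in 12, 12 and 11 and fell in 1, 1 and 3 of 25 cases, the same adjusted over the list alone (adjusted p = 0.377, 0.367 and 0.396). Ribosomal protein genes rose in 8, 6 and 12 of 22 cases with 0 falls, 7, 4 and 12 adjusted over the list alone (adjusted p = 0.396, 0.318 and 0.0979). Ribosome biogenesis genes rose in 5, 4 and 7 and fell in 4, 5 and 2 of 21 cases, 3 falling at 6 h adjusted over the list alone (adjusted p = 0.716, 0.377 and 0.763), with a downward test at 6 h beside a median of 0.02. Aminoacyl-tRNA synthetase genes rose in 9, 7 and 5 and fell in 1, 1 and 3 of 17 cases, the same adjusted over the list alone (adjusted p = 0.396, 0.476 and 0.98), with a downward test at 48 h beside a median of 0.04. Dopamine signalling genes rose in 8, 7 and 7 and fell in 4, 3 and 5 of 21 cases, 9 rising at 6 h adjusted over the list alone (adjusted p = 0.967, 0.943 and 0.629), with downward tests at 24 h and 48 h beside medians of 0.09 and 0.04. Xenobiotic response genes rose in 3, 2 and 3 and fell in 1, 2 and 1 of 11 cases, 3, 1 and 2 rising adjusted over the list alone (adjusted p = 0.786, 0.869 and 0.875), with downward tests at 6 h and 24 h beside medians of 0.07 and 0.09. Of markers of other cells, Schwann cell genes rose in 3, 4 and 3 and fell in 1, 1 and 2 of 7 cases, 2 falling at 24 h adjusted over the list alone (adjusted p = 0.79, 0.763 and 0.769, median 0.16 and mean -0.04 at 6 h). Endothelial and immune genes rose in 1, 0 and 0 and fell in 1, 1 and 1 of 6 cases, the same adjusted over the list alone (adjusted p = 0.583, 0.525 and 0.34), with downward tests at 6 h and 24 h beside medians of 0.04 and 0.05.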
